A study of Mus musculus with 30 samples.

How the data were processed

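Hippocampal RNA from 30 mice was sequenced, 6 per diet and 3 of each sex within a diet. Per the labels' protocols, libraries were made with a stranded poly(A) kit and read on an Illumina HiSeq for 100 cycles from one end. The strand setting used for quantification is not given in the sources used here, so overlapping and antisense genes are uncertain. Per the submitters' processing notes, bcl2fastq 2.18.0, TopHat2 2.0.14, StringTie 1.2.4, featureCounts 1.4.6 and DESeq2 1.16.1 were used with the mm10 build, and the notes as used here do not give the role of each.

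The authors deposited a table of FPKM per transcript, with 46109 rows, of which 43994 are Ensembl transcripts and 2115 are named by location. FPKM divides by transcript length and by the size of each library, so it keeps no depth, and the depth is unknown. A missing value means that a library did not list the transcript, which is not the same as 0. Only 6858 rows had a value in all 30 libraries, 2703 had one in none, and the median row had values in 11. An exact 0 may be a failed estimate: of the 4447 transcripts tested, 887 had at least 1 value of 0, together 7898 of 133410 values. The design had been written for genes, and transcripts were tested in their place, since the table holds transcripts. A change of one transcript may therefore be a shift between isoforms of a gene. Between 70.3 and 72.1 percent of a library's summed FPKM was in the tested transcripts.

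Values were tested as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), two-sided, with sex as a covariate and all 30 libraries sharing 1 estimate of spread. Transcripts needed a value in every library and a mean FPKM of at least 1. Adjusted p-values are Benjamini-Hochberg values over the 4447 transcripts of a comparison, with a threshold of 0.05. The trend used the 18 libraries of the P diets. The comparisons overlap in their libraries, and no adjustment was made across comparisons.

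Of 40 gene and marker lists fixed before the data were examined, 32 had at least 3 measured members, with 1 transcript per gene, that of highest mean FPKM. They were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the lists of a comparison. Fry asks if members move one way on balance and does not compare them with other genes. List scores of single libraries were compared by exact permutation, which was chosen after the data had been seen. Listing of Xist and Y-linked transcripts was counted per sex.

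The rule for named genes, written before the data were examined, takes for each diet against Chow and for the mean of the P diets up to 10 rises and 10 falls past the threshold, fills up to 20 by the smallest p, and lets predicted genes be counted without being named. It adds up to 4 members of each list that passed and the fixed genes Fkbp5, Sgk1, Sirt1, Ppargc1a, Mtor, Bdnf, Igf1, Npy, Gfap and Ttr. A transcript that the rule names in ChowCR against Chow is not reported here. Transcripts named for the P diets against ChowCR or for sex fall outside it. Coordinates come from GENCODE M21 (GRCm38), in which 43416 of the 43994 transcript identifiers were found. Gm15525's transcript was not among them.

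The procedure was tested on simulated data for ChowCR against Chow, with 200 of 4447 transcripts changed in each of 10 simulations. It recovered 17.9 percent of transcripts changed by 0.5 on the log2 scale, 45.8 percent of those changed by 1 and 76.4 percent of those changed by 2, and 4.71 percent of its calls were false. Simulated values were normal and independent between transcripts, with the real means and spreads. They did not imitate the exact zeros of the real values, so rates in the real data may differ. The Benjamini-Hochberg threshold is also stricter when fewer than 200 transcripts change, so recovery in the real comparisons may be lower. Most changes of 0.5 or less would be missed in data of the simulated kind.

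Alternatives planned in advance were other pseudocounts, filters and scalings, no sex covariate, robust and weighted fits, the compared groups alone, Ttr or myelin genes as covariate, each sex alone, and each library left out in turn. Chosen after seeing the data were transcripts above 0 in every library, transcripts listed in at least 24 libraries, FPKM summed per gene symbol with unlisted transcripts at 0, and protein-coding transcripts alone. For the lists, the Ttr covariate, each sex alone and leaving out libraries were also chosen then.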

Results

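RNA was sequenced from the whole hippocampus of 30 mice aged 15 months, 6 on each of 5 diets. The diets are named Chow, ChowCR, 5% P, 10% P and 15% P, and the series title sets low protein, high carbohydrate diets beside caloric restriction. CR is read here as caloric restriction and P as protein from that title, and the composition of the diets is not given in the labels. Each diet had 3 males and 3 females, described in the series as biological replicates. The values are FPKM (fragments scaled by transcript length and library size) per transcript, and a transcript had a value only in the libraries that listed it. Each library listed between 19681 and 21853 transcripts. The depth is unknown, because the file gives no read counts. The comparisons cover the 4447 transcripts of 3725 gene symbols with a value in all 30 libraries and a mean FPKM of at least 1. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low transcripts.

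The sex labels could be compared with transcripts of the sex chromosomes. Xist, the RNA that coats the inactive X chromosome, was listed in 15 of 15 female libraries at 5.45 ± 0.94 FPKM (SD, n = 15) and in 0 of 15 male libraries. The best listed transcript of the Y-linked Eif2s3y was listed in 15 of 15 male libraries at 3.92 ± 2.03 FPKM (SD, n = 15) and in 0 females, and that of Ddx3y in 14 males and 0 females. Another Ddx3y transcript was listed in 1 female at 0.0354 FPKM and in 11 males, Kdm5d in 1 female at 0.0057 FPKM and in 6 males, and Uty in 10 males and 0 females. By Xist and Eif2s3y, no library went against its sex label.

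Ttr, the thyroid hormone carrier made in large amounts by the choroid plexus, ranged from 7.16 to 7513 FPKM between libraries. It was above 1000 FPKM in 3 Chow, 3 ChowCR, 1 5% P, 1 10% P and 2 15% P libraries. Its log2 difference from Chow was -3.76 with a standard error of 1.98 in 5% P (limma, adjusted p = 0.88), so diet did not separate it beyond the spread between animals. It was the only choroid plexus marker among the transcripts tested.

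**Figure D1:**
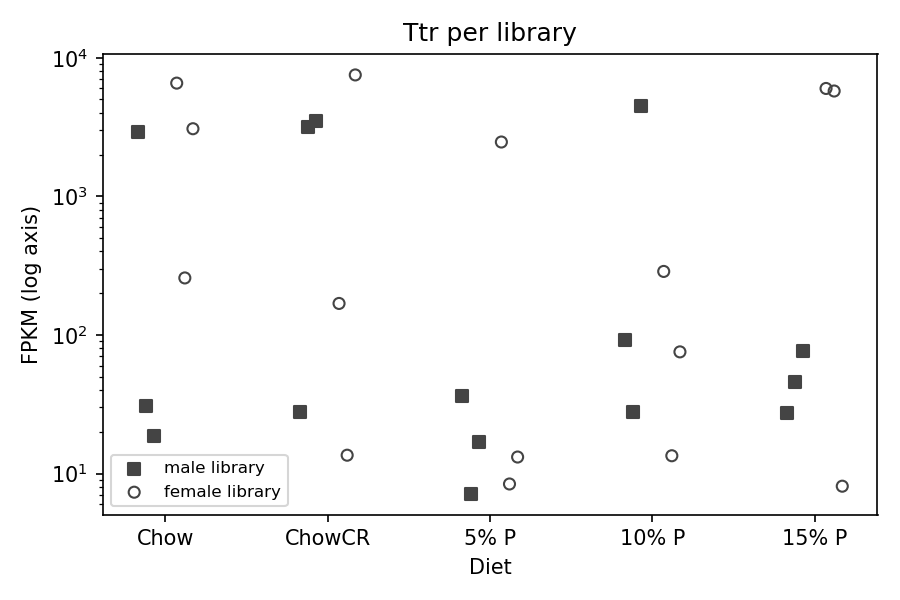
Ttr in FPKM on a log axis for each library, by diet, with filled squares for males and open circles for females. The values run from 7.16 to 7513 FPKM, and libraries above 1000 FPKM occur in all 5 diets.

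The first comparison asks what caloric restriction changed in the hippocampus of mice on chow. Map1s, which encodes a microtubule-associated protein that also binds the autophagy machinery, rose from 9.25 ± 1.28 FPKM in Chow to 14.7 ± 1.27 FPKM in ChowCR (SD, n = 6 each). Its log2 fold change was 0.65 with a standard error of 0.11 (limma, adjusted p = 0.0060). The lowest ChowCR library, at 13.2 FPKM, lay above the highest Chow library, at 11.2 FPKM. The transcript, ENSMUST00000019405.2, is protein coding and lies on chromosome 8 from 70905932 to 70917527 on the plus strand of GRCm38, the assembly also called mm10. The predicted gene Gm15525 also rose, by a log2 fold change of 2.37 with a standard error of 0.38 (limma, adjusted p = 0.0059), from 0.27 ± 0.15 FPKM in Chow to 3.99 ± 3.04 FPKM in ChowCR (SD, n = 6 each). The log2 fold change of Gm15525 was 3.37 with a pseudocount of 0.1 and 1.82 with a pseudocount of 1. These 2 were the transcripts past the threshold of the 4447 tested, and 303 had an unadjusted p under 0.05 where 222.4 were expected by chance. That expected number has no spread for transcripts that vary together. The 303 was not set beside other groupings of these libraries, so it does not show an excess. Both calls ended when the 12 Chow and ChowCR libraries were fitted alone, with the same fold changes and adjusted p = 0.23 for Map1s and 0.11 for Gm15525. They also ended in each sex alone, with log2 differences for Map1s of 0.85 in females (limma, adjusted p = 0.089) and 0.45 in males (0.77), and for Gm15525 of 2.19 in females (0.26) and 2.55 in males (0.23).

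**Figure D2:**
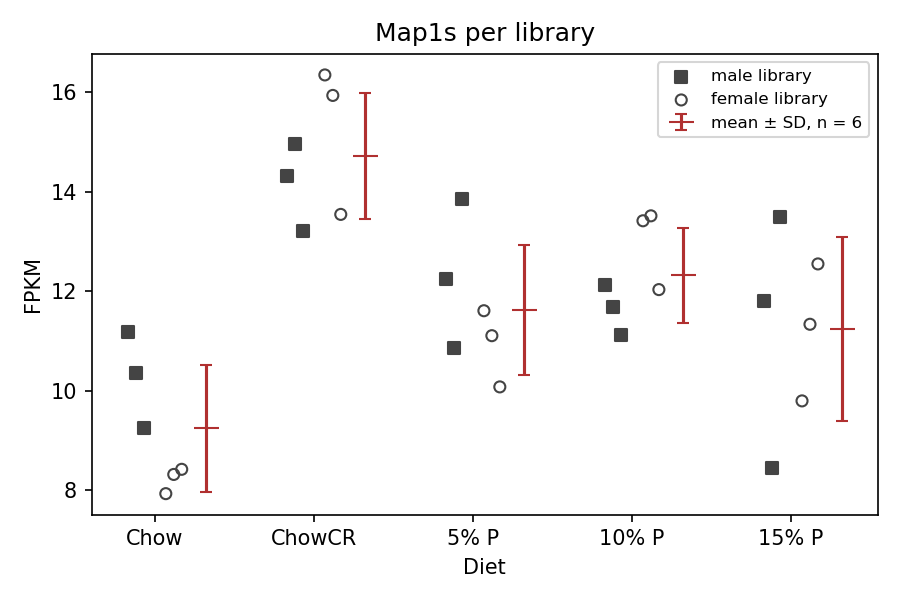
Map1s in FPKM for each library, by diet, with filled squares for males, open circles for females, and the mean and SD of 6 libraries in red. ChowCR averages 14.7 FPKM and Chow 9.25 FPKM, with no overlap between their libraries.

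Other transcripts with small p-values in ChowCR did not pass. Aldoa, the glycolytic enzyme aldolase A, was at 646 ± 80.3 FPKM in Chow and 798 ± 35.8 FPKM in ChowCR (SD, n = 6 each), a log2 difference of 0.31 (limma, adjusted p = 0.10). Pabpn1, a nuclear poly(A)-binding protein, had a log2 difference of 0.46 (limma, adjusted p = 0.10). Cited2, a transcriptional co-regulator, had 0.55. Agap2 had 0.30, Igsf8 0.28, Rbm42 0.76, Akr1a1 0.58, Rsph3a 0.51, Marcksl1 0.70, Fbxo28 2.03 and Mlf2 1.23. The Akr1a1 transcript is annotated as a processed transcript and not as protein coding. Lower values were seen for Csnk1a1, a casein kinase, at -0.55, and for the synaptic vesicle protein Syngr1 at -1.72. Of the 20 transcripts named by the rule, 17 were higher and 3 lower in ChowCR, with adjusted p between 0.0059 and 0.24.

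No gene list passed in ChowCR against Chow, of 32 that could be tested, and the smallest adjusted p was 0.55 (camera). Subunits of oxidative phosphorylation had 32 of 47 members higher, with a mean log2 difference of 0.025. Genes of cholesterol synthesis had 7 of 9 members lower, with a mean of -0.19. The 5 measured genes among sirtuins and energy sensors had a mean of 0.27 and the 6 of insulin and IGF signalling a mean of 0.24, with 4 and 6 members higher. The 7 circadian clock genes had a mean of -0.097, the 10 mTOR pathway genes a mean of 0.023, and the 15 autophagy and lysosome genes a mean of -0.065. Members of cytosolic heat shock split evenly, 5 higher and 5 lower, and their mean of 0.071 differed in sign from the downward direction of the camera test. The same held for the mTOR pathway.

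The next comparisons ask what each P diet changed relative to Chow. No transcript passed in 5% P, 10% P or 15% P (limma), and 242, 279 and 234 had an unadjusted p under 0.05, against 222.4 expected. Without Chow replicate 4 or 10% P replicate 4, 1 transcript passed in 10% P. Without 15% P replicate 5 or 6, 1 passed in 15% P. With only the groups compared, the pseudogene Gm12350 passed in 15% P, at a log2 difference of 7.49 (limma, adjusted p = 1.32e-11). With all 30 libraries the smallest adjusted p of any transcript in 15% P was 0.097 (limma). It was 0.64 with transcripts above 0 in every library. For the mean of the P diets against Chow 0 transcripts passed, with 265 at an unadjusted p under 0.05. Leaving out 1 library gave up to 4 calls for that mean, with 4 without Chow replicate 3, 2 without Chow replicate 2, Chow replicate 4 or 15% P replicate 2, and 1 without Chow replicate 1, Chow replicate 5, 5% P replicate 3 or 15% P replicate 4. Ubl5, a ubiquitin-like protein, had the smallest p in 10% P, with a log2 difference of -1.95 and a standard error of 0.38 (limma, adjusted p = 0.090). Its difference was -1.64 in 5% P and -1.51 for the mean of the P diets. Syngr1 had -1.67 in 5% P, -1.99 in 10% P and -1.67 for the mean of the P diets. Dnajb11, a co-chaperone of the endoplasmic reticulum (ER), had 0.44 in 5% P, 0.56 in 15% P and 0.46 for the mean of the P diets. Chmp4b, a subunit of a membrane-remodelling complex, had 0.59 in 5% P and 0.65 in 10% P. Map1s had 0.40 in 10% P and 0.33 for the mean of the P diets (limma, adjusted p = 0.34).

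Further values that did not pass are given for each diet. In 5% P they include Tcf4 at 2.98, Fubp1 at -2.19, Mgll (ENSMUST00000163271.5) at 2.40, Ddx24 at 0.48, Nmt1 at -0.90, Ogt at -0.96, Coa3 at -1.60 and Ghitm at -1.04. The Ogt transcript is annotated as a retained intron and not as protein coding. In 10% P they include Pcmt1 at -0.59, Fez1 at -0.40, Bsg at -1.21, another Mgll transcript (ENSMUST00000089449.2) at -1.37, Pik3c3 at -0.40, Tmem183a at 1.71, Gucy1b3 at -0.28, Cited2 at 0.45, Gpm6b at -0.78, Gnaq at 1.92 and Slc32a1, the vesicular GABA transporter, at 1.28. In 15% P they include Arl6ip5 at -0.24, Fam210a at -1.68, Coa6 at 1.12, Yars at -0.46, Sdc2 at -1.31, Rsph3a at 0.41, Csnk1a1 at -0.44, Cav1 at -1.16, Ube2ql1 at 1.37 and Ndufs4 at -1.02.

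The list of ER chaperones and unfolded protein response genes rose in 15% P. Of its 20 genes, 8 were measured (Calr, Dnajb11, Pdia3, Ppib, Pdia6, Xbp1, Hspa5 and Manf), and 7 of these were higher than in Chow, with a mean log2 difference of 0.32 (camera, adjusted p = 4.3e-05). The list held with an estimated correlation (adjusted p = 0.032) and with fry (adjusted p = 0.012). Its score, the mean log2 value of the 8 genes, was 4.91 ± 0.14 in Chow and 5.23 ± 0.18 in 15% P (SD, n = 6 each), and 5 of 6 libraries of 15% P lay above the highest Chow library (two-sided exact permutation test, p = 0.0087). The list was picked for this test because it had passed in the same libraries, so that p is not independent evidence. Chow replicate 1, which stood apart on the first principal component (-15.2), had the lowest Chow score, and without it the list held (camera, adjusted p = 0.00059). Dnajb11 was at 14.6 ± 3.97 FPKM in Chow and 21.2 ± 1.92 in 15% P (SD, n = 6 each). Xbp1, a transcription factor of the unfolded protein response, was at 15.4 ± 3.52 and 21.1 ± 1.89 FPKM, and the disulfide isomerase Pdia6 at 31.9 ± 6.44 and 41.5 ± 2.46 FPKM (SD, n = 6 each). These 3 genes passed when adjusted over the list alone, and 0 passed over all transcripts tested. With females alone the list missed the threshold (camera, adjusted p = 0.061).

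**Figure D3:**
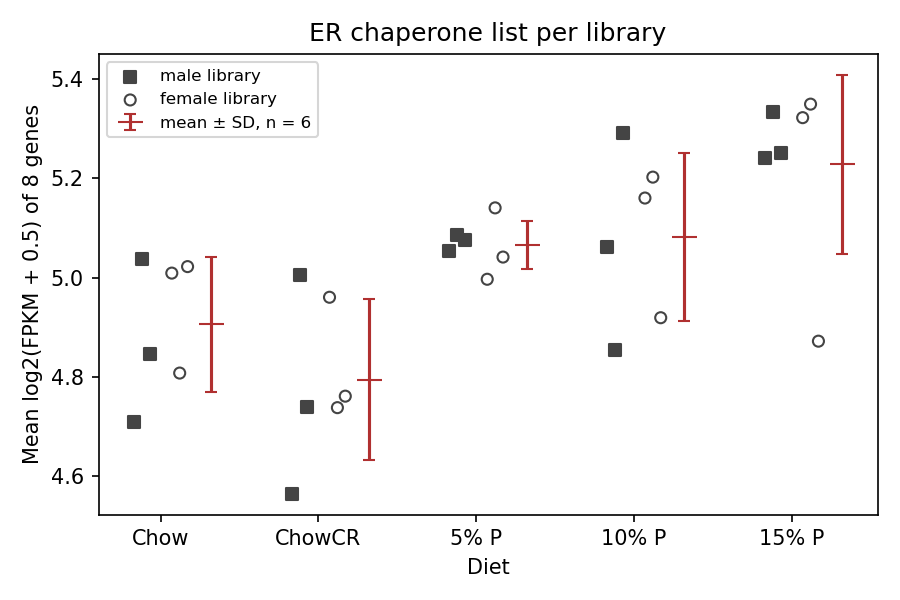
Mean log2(FPKM + 0.5) of the 8 measured ER chaperone genes for each library, by diet, with filled squares for males, open circles for females, and the mean and SD of 6 libraries in red. The group means are 4.91 in Chow, 4.80 in ChowCR, 5.07 in 5% P, 5.08 in 10% P and 5.23 in 15% P.

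The same list was also higher for the mean of the P diets, with 8 of 8 members higher and a mean log2 difference of 0.22 (camera, adjusted p = 0.00094). That call was lost with an estimated correlation (adjusted p = 0.11) and in females alone (adjusted p = 0.193) and held with fry (adjusted p = 0.031), and 2 genes passed when adjusted over the list alone. In 5% P the mean difference was 0.16 (camera, adjusted p = 0.12) and in 10% P it was 0.18 (camera, adjusted p = 0.14), and neither passed. Cytosolic heat shock genes rose in 15% P, with 9 of 10 members higher and a mean of 0.36 (camera, adjusted p = 0.012), a call that was lost with an estimated correlation (adjusted p = 0.14). It was also lost with fry (adjusted p = 0.298), in males alone (0.379) and with transcripts listed in at least 24 libraries (0.174), and the cytosolic heat shock response in 15% P vs Chow missed the threshold with a mean FPKM of at least 5 (0.0594). Its members include Hspa1a at 1.55, Hspa1b at -0.12 and Hsph1 at 0.93, none of which passed, and Hspa1a and Hspa1b are near-identical copies whose reads are hard to tell apart. Leaving out 1 library also ended the heat shock call for Chow replicate 1 (camera, adjusted p = 0.086), Chow replicate 2 (0.15), 15% P replicate 2 (0.065) and 15% P replicate 6 (0.076). No other list passed in a P diet against Chow.

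The low protein diets were next compared with caloric restriction itself. ER chaperone genes were higher in each P diet than in ChowCR, where their score was 4.80 ± 0.16 (SD, n = 6). The mean log2 difference was 0.27 in 5% P (camera, adjusted p = 0.0014), 0.29 in 10% P (camera, adjusted p = 0.00059) and 0.43 in 15% P (camera, adjusted p = 2.9e-07). With an estimated correlation the call held in 15% P (adjusted p = 0.0054) and was lost in 5% P (adjusted p = 0.14) and 10% P (adjusted p = 0.093). In males alone it was also lost in 5% P (adjusted p = 0.103) and 10% P (0.0764), and in 5% P with fry (0.0656). In 15% P, 4 of the 8 genes passed when adjusted over the list alone, and Pdia6 had the largest difference, 0.63 with a standard error of 0.13 (limma, adjusted p = 0.091 over all transcripts). Heat shock genes were also higher in 15% P than in ChowCR, with a mean of 0.29 (camera, adjusted p = 0.00038, and adjusted p = 0.024 with an estimated correlation), a call that was lost in males alone (adjusted p = 0.105). Chordc1, a co-chaperone, was at 17.3 ± 2.03 FPKM in ChowCR and 25.95 ± 2.78 FPKM in 15% P (SD, n = 6 each), a log2 difference of 0.57 (limma, adjusted p = 0.063), and passed in some alternatives, such as median-ratio rescaling (limma, adjusted p = 0.029). The lists in 10% P and 15% P against ChowCR were tested after the data had been seen. The numbers that end the sample titles ran from 97.3 to 122.3 in ChowCR, above those of every other diet. Their meaning is not given, and a batch that followed them could not be told apart from ChowCR.

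No single transcript passed between the P diets and ChowCR (limma), and 300, 247 and 291 had an unadjusted p under 0.05 in 5% P, 10% P and 15% P. The 5 transcripts with the smallest p in each were picked after their values were seen. They include Far1 at 0.89, the clock gene Nr1d1 at -0.59 and Rtn3 at -2.17 in 5% P, Htra1 at 0.64 in 10% P, and Pabpn1 at -0.52 in 15% P (limma, adjusted p = 0.063). The Far1 transcript is annotated as a retained intron and not as protein coding. Pabpn1 in 15% P passed in some alternatives, such as the transcripts with a mean FPKM of at least 5 (limma, adjusted p = 0.038).

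Protein content among the P diets was then tested. Between 5% P and 15% P 0 transcripts passed (limma) and 199 had an unadjusted p under 0.05. For the trend over 5, 10 and 15 percent protein 0 passed and 192 had an unadjusted p under 0.05. No list passed for the trend, where the smallest adjusted p was 0.27 (camera). Over all diets together the limma F test gave 0 transcripts, with 265 at an unadjusted p under 0.05.

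The fold changes of the P diets were set beside those of ChowCR, across transcripts, which are not independent replicates. The correlation was 0.50 for 5% P, 0.51 for 10% P and 0.53 for 15% P. All share the Chow libraries, and unchanged groups simulated against the same number of Chow libraries gave 0.50 for each. The covariances were 0.162, 0.161 and 0.170, against simulated values of 0.158, 0.159 and 0.158. With the Chow libraries split 3 to 3 over 10 splits, the mean correlations were 0.013, 0.011 and 0.030.

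Genes fixed in advance for their links to diet, stress or glia showed no call. The astrocyte gene Gfap was at 99.2 ± 36.3 FPKM in Chow, 106 ± 13.3 in ChowCR and 125 ± 19.4 in 5% P (SD, n = 6 each), with log2 differences of 0.24 and 0.47. Npy, a neuropeptide of interneurons, was at 44.1 ± 24.7 FPKM in Chow and 52.2 ± 13.6 FPKM in ChowCR (SD, n = 6 each). Sgk1, a glucocorticoid-responsive kinase, was at 32.3 ± 13.6 FPKM in Chow and 26.4 ± 9.83 FPKM in ChowCR (SD, n = 6 each). The sign of differences in Gfap, Npy, Sgk1 and Ttr changed under some alternatives, and without Chow replicate 1 Gfap was at -0.078 in ChowCR and 0.15 in 5% P. At least 1 transcript of Ppargc1a was listed in 1 Chow, 4 ChowCR, 3 5% P, 4 10% P and 4 15% P libraries. At least 1 transcript of Sirt1, Mtor, Bdnf and Igf1 was listed in 19, 22, 29 and 7 of the 30 libraries. None of these genes had a transcript in the limma tests. Listing was compared per transcript between Chow and each other diet, and 0 of 34469 passed (Fisher's exact test). The smallest unadjusted p was 0.0022 with 6 against 6 libraries, so that test could detect little. The counts for Ppargc1a are therefore no evidence of a difference between diets. Fkbp5 was not analysed here.

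Males and females were compared within the same fit. No transcript passed (limma), and 246 had an unadjusted p under 0.05. The sex chromosome transcripts above were not in this test, because they were not listed in all 30 libraries. The test for an effect of sex that differs between diets passed for 4 transcripts, named after their values were seen. They were Gm4459 (limma F test, adjusted p = 3.3e-13), Gm10031 (7.8e-10), Thap11 and Gm6341 (0.00084 each). Gm4459, a processed pseudogene on chromosome 7, was at 42.4, 40.2 and 53.5 FPKM in the 3 Chow females and listed at 0 in the other 27 libraries. Gm10031 was listed at 0 in the 3 Chow males and lay between 8.11 and 20.2 FPKM elsewhere. Thap11 was listed at 0 in 12 libraries, including the 3 ChowCR females, the 3 5% P males and the 3 15% P females. Libraries all at 0 have no spread, and each diet had 3 of each sex, so the p-values of these 3 transcripts overstate the certainty. With transcripts above 0 in every library 1 call was made, and 2 were made with a mean FPKM of at least 5 or with protein-coding transcripts alone.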

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

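The tests of the Ttr covariate and of single libraries for the ER chaperone list, and of ChowCR against the P diets for Map1s, were chosen only after the result was seen.

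ER chaperone genes were higher in 15% P than in Chow, with a mean log2 difference of 0.32 over 8 genes (camera, adjusted p = 4.3e-05). With Ttr as a covariate the mean difference was 0.342, and with the number of transcripts listed it was 0.376, which argues against either as the whole cause. The highest adjusted p with any 1 library left out was 0.00066, which argues against a single library. Of 100 splits, 1, the real one, gave a list p as small (1.34e-06, next 1.55e-05). That share is the smallest that 100 splits can give and was not adjusted over the comparisons. Its splits did not keep the sexes balanced within diets as the real groups do. Chance is therefore made less likely but is not excluded. Other batches were not tested, since the labels name none, and an effect of diet stays open as a hypothesis. The numbers that end the sample titles overlap between Chow (1.3 to 50.3) and 15% P (19.3 to 88.3), and their meaning is not given. With females alone, ER chaperones and unfolded protein response in 15% P vs Chow missed the threshold (camera, adjusted p = 0.0607), and the effect of sex on the list was not tested.

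Map1s was higher in ChowCR than in Chow, in 6 of 6 libraries above the highest Chow library. The 12 libraries alone gave the same log2 difference of 0.65 with a standard error of 0.109, beside 0.11 in all 30, and the call ended (limma, adjusted p = 0.23) because fewer libraries remained to estimate the spread. The equal standard errors show no narrowing of its spread by the other diets, though their own precision was not tested, and the exact permutation p of 0.00216, the smallest that 6 against 6 can give, excludes nothing, because Map1s was picked among 4447 transcripts from these same libraries. Low Chow libraries alone stay open because of that choice, although ChowCR lay 0.321 above the mean of the P diets (limma, standard error 0.089, adjusted p = 0.32). The numbers that end the sample titles ran from 97.3 to 122.3 in ChowCR, above those of every other diet. Their meaning is not given, and a batch that followed them could not be told apart from ChowCR. An effect of caloric restriction stays open as a hypothesis. Of 100 splits, 1, the real one, gave as many calls (2, highest other 1), a share under the bound of 0.05 set beforehand. That share was not adjusted over the comparisons, and its splits did not keep the sexes balanced within diets. Both calls also ended with the 12 libraries alone, so chance is not excluded for the count.

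The limma F test for an effect of sex that differs between diets passed for Gm4459 (adjusted p = 3.328e-13), Gm10031 (7.766e-10), Thap11 (0.000841) and Gm6341 (0.000841). For Gm4459, Gm10031 and Thap11 some diet-and-sex cells were all at 0 and had no spread, so their p-values overstate the certainty. Of 100 assignments of the sex labels within diets, 4, the real one included, gave at least as many calls (real 4, highest other 5). The share was under the bound of 0.05 only narrowly and was not adjusted over the comparisons, so chance is not excluded for the count. Of 887 transcripts with zeros, 3 had them on whole diet-and-sex cells (Gm8482, Gm4459 and Gm10031), where random placement gave 0.19 on average and at most 3. Of 1000 random placements, 1 gave as many, which argues against zeros that fall on libraries at random for these 3 transcripts as a set. The bound set beforehand, above all 1000 placements, was not met. Zeros that fall on libraries at random, whatever the diet and sex, are therefore made less likely but not excluded for the 3 as a set. For Gm4459 or Gm10031 alone that cause was not tested and stays open. The count of calls does not settle this. Gm4459 and Gm6341 are processed pseudogenes, whose reads may be shared with a parent gene, which was not tested. A biological effect of sex and diet stays open and untested.

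Single libraries lay far from the other 5 of their group in 11 of 90 groups of values. For normal values chance marks about 1 in 20 groups, or 4.5. FPKM values can be skewed, and the list scores overlap with their members, so 11 does not show an excess. The number of transcripts listed was 19978 in 10% P replicate 2. The ER chaperone score was 4.872 in 15% P replicate 6, and the heat shock score was 4.461 in 15% P replicate 3. Gm15525 was at 10.07 FPKM in ChowCR replicate 3, where the nearest library had 3.87, and at 2.014 FPKM in 15% P replicate 6. Sgk1 was at 7.698 FPKM in ChowCR replicate 4 and Gfap at 28.17 FPKM in Chow replicate 1. Ttr was at 2465 FPKM in 5% P replicate 2 and 4484 FPKM in 10% P replicate 5. Manf was at 9.61 FPKM in ChowCR replicate 3 and 9.464 FPKM in 10% P replicate 4.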

How the results depend on the processing

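Chosen only after the data were seen were the tests of transcripts above 0 in every library, transcripts listed in at least 24 libraries, protein-coding transcripts and gene sums, and for the lists the Ttr covariate, each sex alone and leaving out libraries. Where a result below changed, the cause was not tested unless one is given.

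Over the alternatives, the 107 results for named genes and transcripts were the same 3100 times, newly passed 24 times, lost their call 6 times and changed sign 52 times, always without passing in either setting. The 6 lost calls were Map1s and Gm15525 in ChowCR with the compared groups alone, females alone and males alone. Counts of transcripts for 10% P against ChowCR, 5% P against 15% P and the protein trend, and lists in ChowCR against Chow, were the same in every alternative run.

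With a mean FPKM of at least 5, calls were 1 in ChowCR against Chow, because Gm15525 was not tested, 1 in 15% P against ChowCR and 2 for sex by diet. Lists were then 1 in 15% P and 3 in 10% P against ChowCR, and the cytosolic heat shock response in 15% P vs Chow had adjusted p = 0.0594. Median-ratio rescaling gave 1 call in 15% P against ChowCR. Array weights gave 2 calls there and 2 lists in 5% P against ChowCR, and turned Ttr in ChowCR to 0.19 and Npy to 0.023 in 5% P, 0.011 in 10% P and 0.066 for the mean of the P diets. With only the groups compared, calls were 0 in ChowCR against Chow and 1 in 15% P against Chow, the pseudogene Gm12350.

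Females alone, with fewer libraries, gave calls of 1 in ChowCR, 2 in 5% P, 1 in 10% P, 2 in 15% P and 2 for the mean of the P diets against Chow, and 1 in 5% P against ChowCR. Gm4459, listed at 0 in all females but the Chow ones, was among the calls in each diet against Chow, and the rest were Sdc2. Gfap turned to -0.22 in ChowCR and -0.15 in 15% P, Npy to 0.089 in 5% P, 0.46 in 10% P and 0.37 for the mean of the P diets, and Sgk1 to -0.22 in 10% P. Lists in females were 1 in 15% P and 0 for the mean of the P diets, and 4, 3 and 4 in 5% P, 10% P and 15% P against ChowCR. The adjusted p of ER chaperones and unfolded protein response in 15% P vs Chow was then 0.0607, and that of the list 0.193 for the mean of the P diets.

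Males alone gave 2 calls in ChowCR against Chow, Dnajc27 at 1.76 and Gm10031, in place of Map1s and Gm15525. They gave calls of 2 in 5% P, 2 in 10% P, 1 in 15% P and 2 for the mean of the P diets against Chow, and 1 in 5% P against ChowCR. Gm10031, listed at 0 in the Chow males, was among the calls in each diet against Chow. Sgk1 turned to 0.47 in ChowCR and -0.082 in 15% P, Npy to -0.38 in ChowCR and -0.42 in 15% P, and Ttr to 2.49 in ChowCR and 0.92 in 10% P. Lists in males were 2 for the mean of the P diets and 0, 0 and 1 in 5% P, 10% P and 15% P against ChowCR. Heat shock had adjusted p = 0.379 in 15% P against Chow and 0.105 against ChowCR, and the ER chaperone list 0.103 in 5% P and 0.0764 in 10% P against ChowCR.

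Transcripts above 0 in every library gave 3 calls in 15% P against ChowCR and 1 for sex by diet, since transcripts with zeros were not tested, and 1 list in 10% P against Chow and 3 against ChowCR. Transcripts listed in at least 24 libraries gave 1 call in 10% P against Chow and 1 between the sexes. Lists there were 2 in 10% P and 1 in 15% P against Chow, and 2 in 5% P and 3 in 10% P against ChowCR, with heat shock in 15% P at adjusted p = 0.174. Protein-coding transcripts alone gave 1 call in ChowCR against Chow, 1 in 15% P against ChowCR and 2 for sex by diet. Gene sums gave 6 calls in ChowCR, 2 in 10% P, 1 in 15% P and 1 for the mean of the P diets against Chow, 3 in 5% P against ChowCR, 1 over all diets, 5 between the sexes and 7 for sex by diet.

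Quantile normalization turned Sgk1 in 10% P to -3e-04 and gave 2 lists in 5% P and 2 in 10% P against ChowCR. Ttr as covariate turned Sgk1 to 0.29 in 5% P and 0.27 for the mean of the P diets, and gave 2 lists in 5% P and 1 in 10% P against Chow, and 3 and 4 against ChowCR. Ttr itself has no value under that covariate. The oligodendrocyte covariate turned Sgk1 to -0.22 in 10% P and -0.26 in 15% P. A pseudocount of 0.1 gave 3 lists in 10% P against ChowCR. Splitting the Chow libraries lowered the correlations of fold changes with ChowCR to 0.013 in 5% P, 0.011 in 10% P and 0.030 in 15% P, which the shared libraries explain.

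With an estimated correlation, lists were 1 in 15% P and 0 for the mean of the P diets against Chow, and 0 in 5% P and 0 in 10% P against ChowCR. Heat shock in 15% P then had adjusted p = 0.137, and the ER chaperone list 0.113 for the mean of the P diets, 0.136 in 5% P against ChowCR and 0.0929 in 10% P against ChowCR. With fry, lists were 1 in 15% P against Chow and 0 in 5% P against ChowCR, with heat shock in 15% P at 0.298 and the ER chaperone list in 5% P against ChowCR at 0.0656.

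With 1 library left out, calls in ChowCR ranged from 2 to 4, with 4 without Chow replicate 1 or 4. Calls ranged from 0 to 1 in 10% P (1 without Chow replicate 4 or 10% P replicate 4), 0 to 1 in 15% P (1 without 15% P replicate 5 or 6) and 0 to 1 in 5% P against ChowCR (1 without ChowCR replicate 1). For the mean of the P diets they ranged from 0 to 4, with 4 without Chow replicate 3, 2 without Chow replicate 2, Chow replicate 4 or 15% P replicate 2, and 1 without Chow replicate 1, Chow replicate 5, 5% P replicate 3 or 15% P replicate 4.

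Lists ranged from 0 to 1 in 5% P (1 without Chow replicate 6), 0 to 1 in 10% P (1 without 10% P replicate 3 or 6), 1 to 3 in 15% P and 1 to 2 for the mean of the P diets (2 without Chow replicate 6, 10% P replicate 6 or 15% P replicate 3). They ranged from 1 to 2 in 5% P against ChowCR (2 without ChowCR replicate 2 or 5, or 5% P replicate 1 or 2), 1 to 4 in 10% P against ChowCR (4 without ChowCR replicate 2 or 5 or 10% P replicate 4, 2 without 10% P replicate 6) and 0 to 2 for the trend (2 without 15% P replicate 6). The adjusted p of the cytosolic heat shock response in 15% P vs Chow ranged from 0.00013 to 0.148, and its call and 1 of the 2 lists ended without Chow replicate 1 (0.086) or 2 (0.148), or 15% P replicate 2 (0.0645) or 6 (0.0759).

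Gfap ranged from -0.078 to 0.33 in ChowCR, -0.018 to 0.39 in 10% P and -0.071 to 0.34 in 15% P, negative each time without Chow replicate 1. Npy ranged from -0.19 to 0.18 in 5% P, -0.19 to 0.17 in 10% P, -0.054 to 0.31 in 15% P and -0.14 to 0.22 for the mean of the P diets. Sgk1 ranged from -0.48 to 0.075 in ChowCR, -0.13 to 0.13 in 10% P, -0.12 to 0.33 in 15% P and -0.16 to 0.063 for the mean of the P diets. The difference of Ttr ENSMUST00000075312.3 in ChowCR vs Chow ranged from -0.94 to 1.04. The depth is unknown, so its limit on these values cannot be given.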

Other observations

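The exact permutation tests of list scores, the gene sums and the tests of transcripts listed in at least 24 libraries were chosen only after the result was seen.

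Other splits of the same libraries were drawn, 100 for each comparison with the real one included. For transcripts with an unadjusted p under 0.05, chance cannot be excluded in 5% P (19 splits as large, real 242, highest other 330), 10% P (11, 279, 310), 15% P (39, 234, 410) and the mean of the P diets (7, 265, 334) against Chow. Nor can it in 5% P against 15% P (67, 199, 316), the protein trend (63, 192, 323) and the sexes (13, 246, 319). The share was under 0.05 for that count in 5% P (1, 300, 267), 10% P (2, 247, 286) and 15% P (1, 291, 272) against ChowCR, and over all diets (2, 265, 273). In 10% P against ChowCR and over all diets, another split gave a higher count than the real one. These comparisons share libraries and the shares were not adjusted over them, so chance is not excluded. In each of them 0 transcripts passed.

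For the smallest list p, chance cannot be excluded in ChowCR (67 splits, real 0.0172, smallest other 0.00018), 5% P (33, 0.0036, 0.000113), 10% P (32, 0.00431, 0.000163) against Chow, or the trend (59, 0.00932, 2.16e-08). The share was under 0.05 for the mean of the P diets (2, 2.94e-05, 2.43e-07). Against ChowCR it was so in 5% P (4, 4.47e-05, 9.35e-06), 10% P (2, 1.84e-05, 1.62e-05) and 15% P (1, 8.96e-09, 1.29e-07). Except in 15% P against ChowCR, another split gave a smaller p than the real one. These comparisons share libraries and the shares were not adjusted over them, so chance is made less likely but is not excluded.

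In 5% P against Chow the ER chaperone list missed the threshold, with adjusted p = 0.115 by camera, 0.592 with an estimated correlation and 0.549 by fry. Its score had an exact two-sided permutation p of 0.0152 there, with 5 of 6 libraries above the highest Chow library, but the list was picked because it had passed in some of the same libraries, so that p is not independent evidence. The score missed the threshold in 10% P (exact p = 0.0779, adjusted p = 0.109). The score of ChowCR did not pass against Chow (exact p = 0.212, adjusted p = 0.27).

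FPKM summed per gene symbol, with unlisted transcripts at 0, passed in ChowCR against Chow for Gm15525, Map1s and Pcdhga10, which were higher, and Grb2, Taf2 and Ttll7, which were lower, at -4.67, -3.53 and -2.54. Grb2 had no listed transcript in 6 of the 30 libraries and Taf2 in 17. Pcdhga10, at 2.46 in ChowCR, also passed in 10% P (2.26), 15% P (2.43) and the mean of the P diets (2.17), and had no listed transcript in 5 libraries. Slc1a3, an astrocyte glutamate transporter, passed in 10% P against Chow at 2.68 in these sums (limma, adjusted p = 0.0467) and at 3.08 with transcripts listed in at least 24 libraries (adjusted p = 0.0142), and was named after its values were seen. The clock gene Dbp fell by 1.51 on the log2 scale in 5% P against ChowCR in these sums. These sums mix expression with whether a transcript was listed.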
